A study of Mus musculus with 4 samples.

How the data were processed

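RNA from sorted bulge stem cells of 4 samples, 2 from mice given CSA and 2 from mice given vehicle, was measured on one-colour arrays. Per the labels' protocols, total RNA was extracted with Trizol LS and a column kit, and 20 ng was amplified in 1 round and turned into biotin-labelled cDNA. Groups and replicate numbers were taken from the sample titles. The series design text calls the replicates biological, and the labels do not say how many mice gave each sample. Nothing in the labels pairs a CSA sample with a vehicle sample of the same number.

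The values are those of the deposited series matrix, 28815 rows for 4 arrays, on a log scale that the authors did not name and that was taken as log2. Each row was centred by the authors on a baseline. That baseline is not the mean or the median of the 4 arrays, since only 11.38% of rows had a median of 0 and 0.08% a mean of 0 (both within 1e-04), and all 4 arrays stood above 0 in 3.66% of rows and below 0 in 3.33%. In 18.6% of rows 2 of the arrays had values of equal size and opposite sign (within 2e-06), as centring on the median of an even number of arrays can give; which arrays entered is not given in the sources used here. The array software, background correction, summarization and normalization are not given in the sources used here, and the submitters' processing notes name only the genome build mm8. If the base were not 2, every fold threshold and difference would scale by 1 factor, while p-values would stay. Array medians were 0.0089 for CSA replicate 1, -0.0204 for CSA replicate 2, 0.0646 for vehicle replicate 1 and -0.0224 for vehicle replicate 2. Standard deviations over rows were 0.408, 0.3721, 0.4732 and 0.3705 in the same order. No scanner values were used here, so no measure of signal over background was available, and the number of arrays limits the precision.

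Rows were named through the platform's annotation. Of the 28815 rows 21780 named 1 gene, 1605 named several and were left out, and 5430 were not listed and stay unnamed here. For 21689 of the rows with 1 gene the identifier was found in a RefSeq gene table of assembly GRCm38, and 0 symbols needed an update. That assembly differs from the build of the submitters' notes, so it served only for names and for the order of neighbouring genes, and no coordinates are printed. The named rows made 19935 genes, 998 of them with more than 1 row. Such a gene was represented by the row with the highest mean over the 4 arrays. As the values are centred, that row is the one farthest above the baseline and not the brightest, and a filter on the mean selects genes the same way.

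Differences were tested with limma 3.58.1 in R 4.3.3 on the values as deposited, with no filter, using lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over 19935 genes and a threshold of 0.05. The fit had no block. The plan written in advance had eBayes with a mean-variance trend. On values centred per row the mean does not track abundance, and the trend gave Cd34 a standard error of 93.8 on the log2 scale, so eBayes without the trend was used in its place; it had been planned as an alternative. This change was made after the fit with the trend had been seen. Both call 0 genes; at an unadjusted p under 0.05 the fit with the trend gives 547 genes and the fit used here 565. The prior degrees of freedom were 2.13. Standard errors are moderated, with each gene's variance drawn towards a value common to all genes, so they are not the spread of its arrays alone. Genes were also counted where the groups stood at least 1.5-fold apart and did not overlap.

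Gene lists were fixed before the data were examined: 26 lists of bulge, hair germ, hair shaft, cell cycle, calcineurin and NFAT, hormone and cytokine, BMP and TGF-beta, Wnt, basement membrane, epidermal, sebaceous, stress, interferon, respiratory, ribosomal and other cell type genes. They were tested with limma's camera at a preset correlation of 0.01, with the correlation estimated from the arrays beside it, and with fry, each adjusted over the 26 lists. Some genes of these lists had no row naming them alone and were not analysed here. Among them was the prolactin receptor gene Prlr, which the fixed set of named genes described next also held. Named genes followed a rule fixed at the same time: the 10 with the smallest p in each direction among genes whose groups did not overlap and whose mean was at or above the median of all genes, as 0 passed, leaving out predicted, clone and receptor cluster names; a fixed set of calcineurin, bulge and cell cycle genes; and up to 4 members of each list with the largest absolute moderated t. With the planned trend 7 of the 10 higher and 8 of the 10 lower genes would be the same. Genes named outside the rule are said to be so.

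The scripts were tested on simulated arrays with the spread of these genes, 20 times, with 200 of 19935 genes changed. limma called 0.2% of the genes changed by log2 of 1, 14.8% at 2, 62.5% at 3 and 79.1% at 4. It gave the right direction for 97.4% at log2 of 1, and 5.01% of unchanged genes had an unadjusted p under 0.05; 88 false calls were made over all simulations. For lists of independent genes with no change, camera made 0 calls with either setting.

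Alternatives planned in advance were a replicate block, quantile normalization, arrays centred on their medians, filters at the 25th and 50th percentile of the mean, the mean of a gene's rows, each array left out in turn, the trend with and without robust moderation, an unmoderated test, every row of the table, a 2-fold threshold, and camera with an estimated correlation or on ranks. A pseudocount did not apply to log values. When an array was left out, the lone array of its group was assumed to vary like the other group. Percentiles of gene sets came from 10000 random sets and intervals of 95% from as many bootstrap samples of the genes, with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15; figures were drawn with matplotlib 3.10.9.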

Results

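The study compared bulge stem cells of the hair follicle from mice given CSA with the same cells from mice given vehicle. The bulge is the region of the follicle that holds its resting stem cells. The labels do not spell CSA out; in work on calcineurin the abbreviation stands for cyclosporine A. That drug inhibits this phosphatase and so keeps transcription factors of the NFAT family out of the nucleus. The series title places the comparison in the question of how calcineurin and Nfatc1 bear on the quiescence of skin stem cells and on hormonal signalling. Male CD-1 mice at postnatal day 56, in the second telogen (the resting phase of the hair cycle), received 100 mg/kg CSA or vehicle in the peritoneum for 3 days, and cells carrying both CD34 and alpha6 integrin were sorted from the skin.

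RNA of 2 biological replicates per group was measured on 4 one-colour arrays, and their number limits the precision of every value below. The table held 28815 rows, of which 19935 genes could be named. The array medians were 0.01 for CSA replicate 1, -0.02 for CSA replicate 2, 0.06 for vehicle replicate 1 and -0.02 for vehicle replicate 2, on a log scale taken as log2. Each row was centred on a baseline of the authors that is not the mean or median of these 4 arrays and stays unknown. A value therefore says how far a gene stood from that baseline and not how abundant its RNA was. The log base and the normalization between arrays are also unknown, and higher values were taken as more RNA. Across rows, which are not independent replicates, CSA replicate 2 and vehicle replicate 2 had a Pearson r of 0.516, and every other pair of arrays lay between 0.02 and 0.168.

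Serpinb11, a clade B serine protease inhibitor, differed most between CSA and vehicle among all genes. Its values were -0.96 and -0.44 on the CSA arrays and 3.49 and 4.02 on the vehicle arrays. The log2 difference was -4.46 ± 0.30 (limma's moderated standard error, 2 arrays per group, as for every value after ± in this account). Serpinb6c, of the same clade, went the other way and had a mean of 3.38 in CSA against 0.28 in vehicle, a difference of 3.10 ± 0.31. Nrep was lower in CSA by -3.13 ± 0.76 and Serpina3n, a secreted serine protease inhibitor of the acute phase, was higher by 2.71 ± 0.78; both were chosen after their values were seen. Ccnd1, which encodes the G1 cyclin D1, stood at -2.09 and -0.87 in CSA and at 0.01 and 0.07 in vehicle. Cd34, the marker used for the sort, was lower on both CSA arrays (1.75 and 3.60) than on both vehicle arrays (4.05 and 4.25).

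None of these differences passed the test over all genes. limma called 0 of 19935 genes at an adjusted p under 0.05, and its smallest adjusted p was 0.999. At an unadjusted p under 0.05 limma gave 565 genes (365 higher and 200 lower in CSA), where 997 would be reached by chance, and an ordinary test per gene without moderation gave 540. The groups stood 1.5-fold apart without overlap for 1177 genes, 780 higher and 397 lower in CSA. The arrays of both groups did not overlap for 26.3% of genes, against the 33.3% that chance gives for 2 arrays against 2.

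The same count was taken for the other ways of parting the 4 arrays into pairs. Both arrays numbered replicate 1 against both numbered replicate 2 gave 2140 genes 1.5-fold apart, of which 1722 were lower in replicate 1, and 2043 genes at an unadjusted p under 0.05 by limma. The remaining split gave 1088 and 497 genes. By both counts the arrays parted more by replicate number than by treatment. The labels do not say whether the number marks a batch. A fit without a block counts such a difference as spread within the groups. The 1.5-fold count for CSA against vehicle rose whichever array was left out. But 1 array against 2 overlaps less often by itself, so this does not show an array's weight. With all arrays 66.3% of the genes counted were higher in CSA. Without CSA replicate 1 the share was 75.3%, and without CSA replicate 2 it was 49.9%. Without vehicle replicate 1 it was 42.2%, and without vehicle replicate 2 it was 68.8%.

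**Figure D1:**
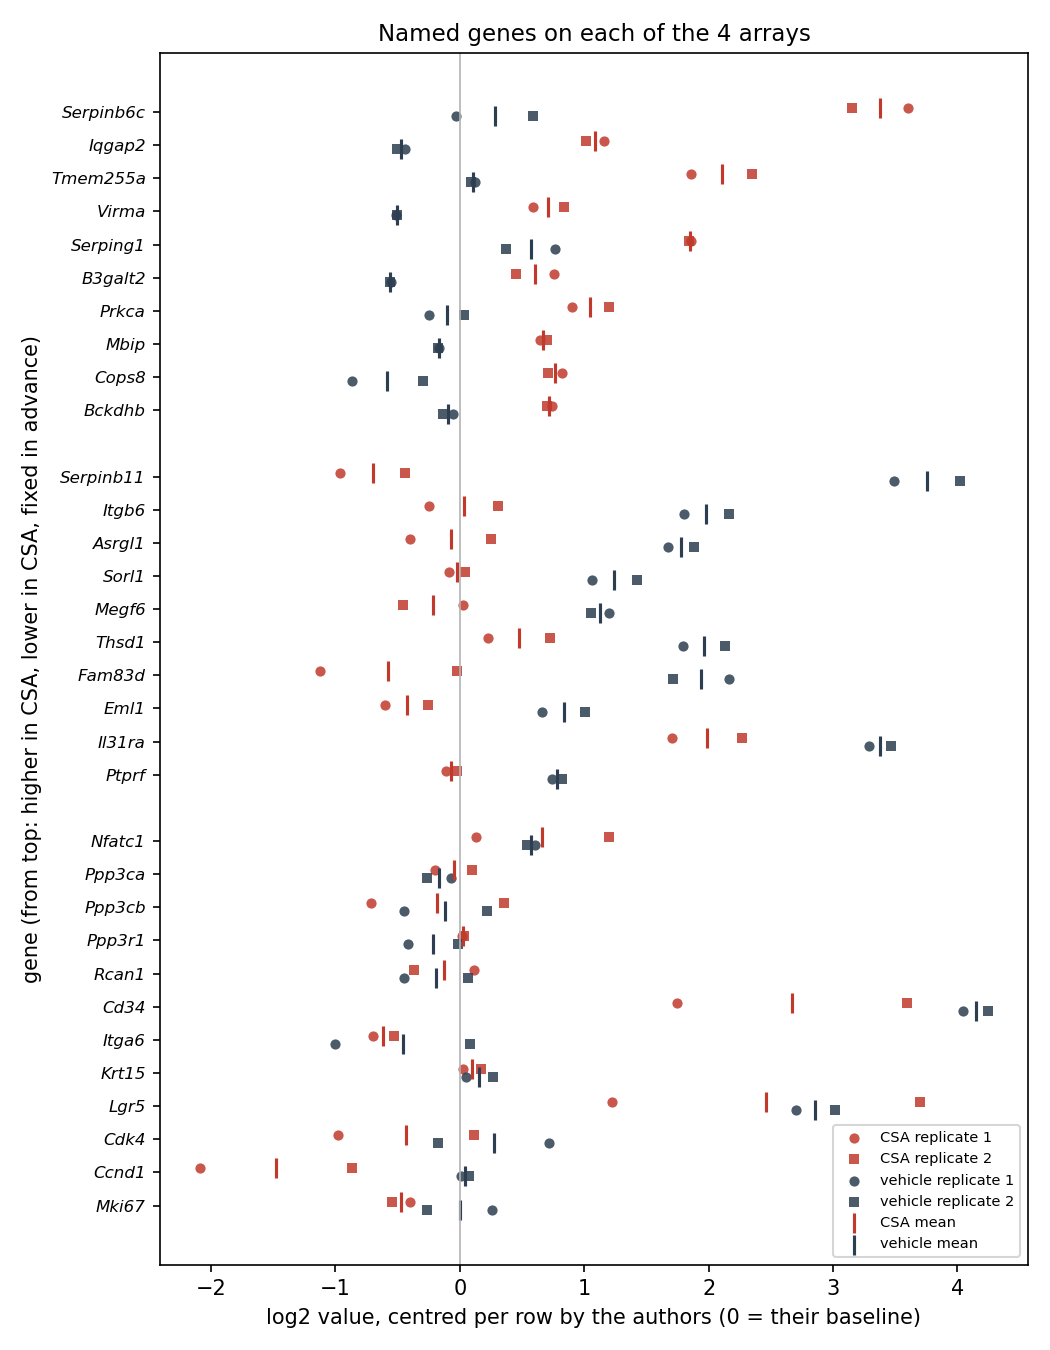
Log2 values, centred per row by the authors, of the named genes on the 4 arrays, with circles for replicate 1, squares for replicate 2, red for CSA, dark blue for vehicle, and vertical ticks for the mean of each group. Serpinb11 stands at -0.96 and -0.44 in CSA and at 3.49 and 4.02 in vehicle, while the 5 calcineurin and NFAT genes Nfatc1, Ppp3ca, Ppp3cb, Ppp3r1 and Rcan1 lie between -0.72 and 1.20 on all 4 arrays.

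The 10 genes higher in CSA that the rule for named genes took did not pass, each with a limma adjusted p of 0.999. After Serpinb6c came Iqgap2, a scaffold protein that binds actin regulators, at 1.56 ± 0.16, and the membrane protein gene Tmem255a at 2.00 ± 0.23. Serping1, the inhibitor of complement component C1, differed by 1.28 ± 0.20 and Prkca, protein kinase C alpha, by 1.15 ± 0.21. Virma, a subunit of the complex that methylates adenosine in mRNA, differed by 1.22 ± 0.18 and the galactosyltransferase gene B3galt2 by 1.16 ± 0.19. Cops8 of the COP9 signalosome differed by 1.35 ± 0.25, Mbip by 0.84 ± 0.15 and Bckdhb, which takes part in the breakdown of branched-chain amino acids, by 0.81 ± 0.16.

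The genes lower in CSA by the same rule did not pass either, with the same limma adjusted p. Itgb6, the integrin beta subunit whose dimer with Itgav activates latent TGF-beta, had means of 0.03 in CSA and 1.98 in vehicle and differed by -1.95 ± 0.28. Il31ra, a cytokine receptor chain, was far above the baseline on all 4 arrays and lower in CSA (means 1.99 and 3.37, difference -1.39 ± 0.26). Fam83d, a spindle protein, differed by -2.51 ± 0.44, the sorting receptor gene Sorl1 by -1.27 ± 0.20 and Eml1, which binds microtubules, by -1.26 ± 0.23. The receptor phosphatase gene Ptprf differed by -0.85 ± 0.16, Asrgl1 by -1.85 ± 0.28, Thsd1 by -1.49 ± 0.26 and Megf6 by -1.34 ± 0.23.

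Among the calcineurin subunit genes, Ppp3cc, which encodes a catalytic subunit, was 0.91 and 0.16 on the CSA arrays and -1.08 and 0.17 on the vehicle arrays. Its difference of 0.99 ± 0.53 was 0.37 without vehicle replicate 1 and 0.61 without CSA replicate 1. The other catalytic subunit genes Ppp3ca and Ppp3cb differed by 0.12 ± 0.20 and -0.06 ± 0.47, and the regulatory subunit gene Ppp3r1 by 0.24 ± 0.21. Nfatc1 itself was 0.13 and 1.20 on the CSA arrays and 0.60 and 0.54 on the vehicle arrays (0.09 ± 0.40), so that the CSA arrays lay on either side of vehicle. Rcan1, a calcineurin inhibitor that NFAT induces, differed by 0.07 ± 0.29 and by -0.08 after quantile normalization. Of the 25 measured genes of the calcineurin and NFAT pathway list 13 were higher and 12 lower (median 0.07, and -0.02 after quantile normalization; limma camera adjusted p = 0.354), with the calcium channel gene Orai1 at 0.22 ± 0.15. Of 15 NFAT target genes known from immune cells 11 were lower (median -0.11, limma camera adjusted p = 0.141, and 0.789 with an estimated correlation). The list's median was -0.18 without CSA replicate 1 and -0.17 without vehicle replicate 2. It was -0.04 without vehicle replicate 1 and -0.05 without CSA replicate 2. Among the lower genes were Ptgs2, which encodes cyclooxygenase 2, at -1.07 ± 0.28 and the transcription factor gene Egr2 at -0.78 ± 0.56. The groups overlapped for Egr2, and its difference was -0.20 without CSA replicate 2 and -0.28 without vehicle replicate 1.

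Whole gene lists were tested against all other genes, and 9 of 26 stood apart by limma camera with its preset correlation, 7 lower and 2 higher in CSA. Some of these lists share members, so their calls are not independent. The bulge and Wnt lists share Tcf7l1, Tcf7l2, Dkk3, Sfrp1 and Wif1. The bulge and basement membrane lists share Itga6, Col17a1 and Npnt. With the correlation estimated from the arrays 0 of 26 passed (smallest limma adjusted p 0.789). On 4 simulated arrays that setting also missed a list of 28 genes shifted by 0.5 in 20 of 20 simulations, while the preset setting called 5.3 of 26 unchanged lists on average when their members shared a correlation of 0.3. By fry, which asks whether a list's genes moved one way on balance, 0 lists passed (smallest limma adjusted p 0.842), and both of these tests had 0 lists at an unadjusted p under 0.05. Among genes with a mean at or above the 25th percentile the basement membrane, epidermal and oxidative phosphorylation lists kept their limma camera call, and at the 50th the first 2 of these. Over all genes 0 list members passed, and adjusted over the list alone 1 did.

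**Figure D2:**
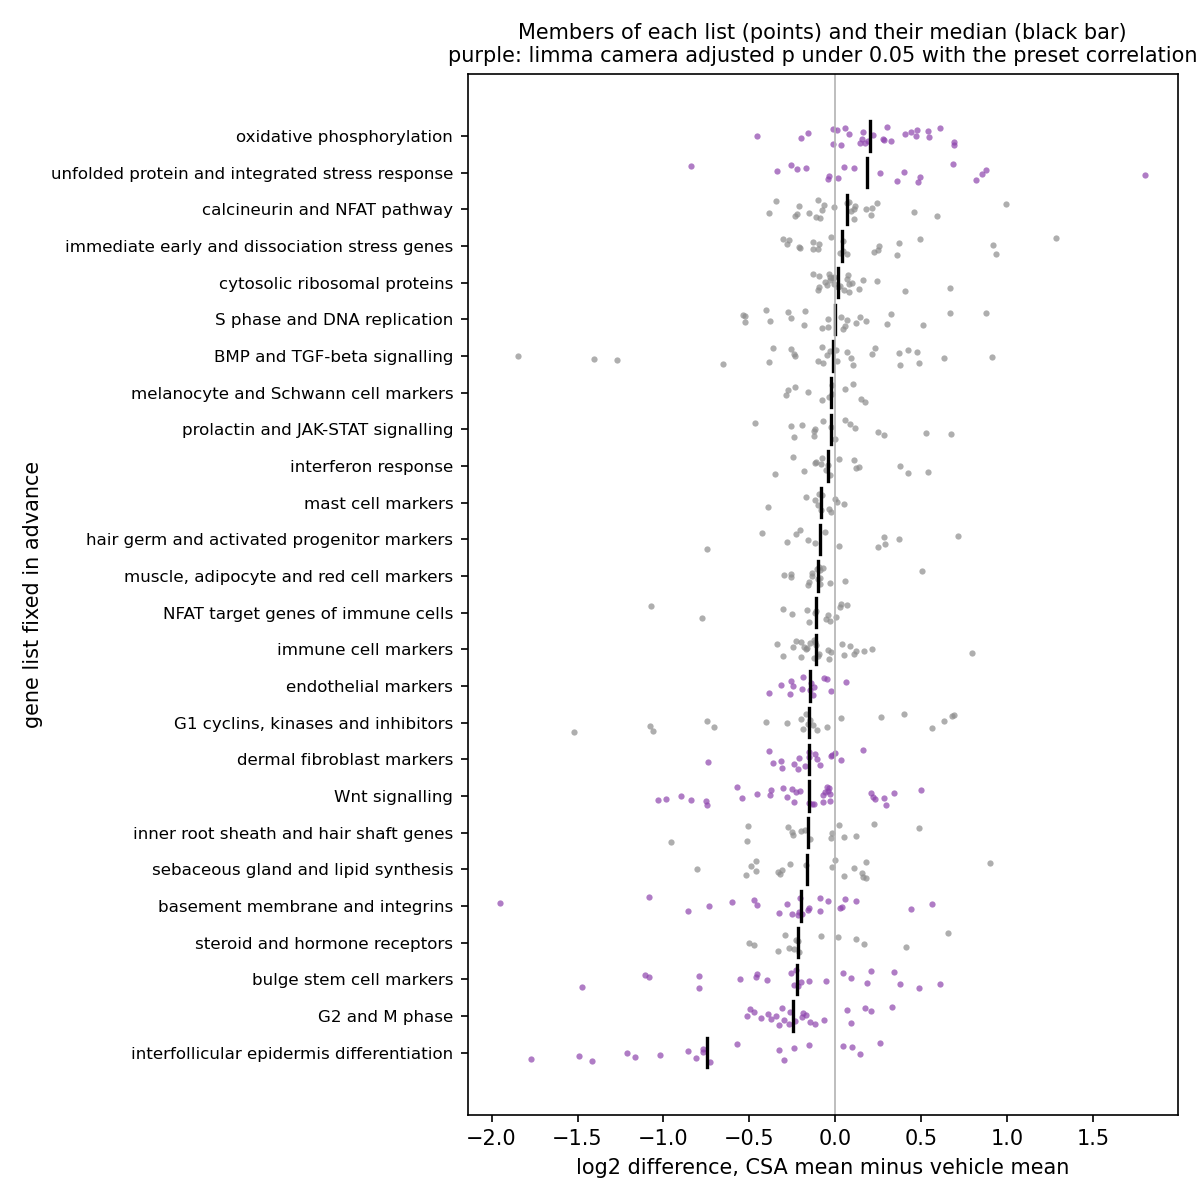
Log2 difference, CSA mean minus vehicle mean, of every measured member (points) of the 26 gene lists, sorted by the median (black bar), with purple for the 9 lists under 0.05 by limma camera with the preset correlation. The epidermal differentiation list has the lowest median (-0.75) and the oxidative phosphorylation list the highest (0.20).

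Genes of the basement membrane and the integrins that hold cells to it were lower in CSA, 19 of 25 (median -0.20, limma camera adjusted p = 0.000633; adjusted p = 0.789 with an estimated correlation, unadjusted 0.106). Itgb6 was the member that passed over the list alone (limma adjusted p = 0.0475), and fry found the members changed in either direction (limma adjusted p = 0.0222). Frem2, a matrix protein under the epidermis, differed by -0.86 ± 0.18, Itgav by -0.74 ± 0.18 and the laminin chain gene Lama3 by -0.60 ± 0.16, while Itga6, the integrin used for the sort, differed by -0.16 ± 0.41. Marker lists of fibroblasts (median -0.16), endothelial cells (-0.15) and differentiated epidermis (-0.75) were lower as well, and the list holds matrix genes that such cells also use. Without vehicle replicate 1 the medians of these marker lists were -0.11, -0.03 and -0.05, while that of the basement membrane list was -0.24. The call was lost without CSA replicate 2 (median -0.11, limma adjusted p = 0.291) and without vehicle replicate 2 (median -0.24, 0.158), and without CSA replicate 1 the median was -0.32 (0.000437).

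Markers of the bulge stem cells were lower in CSA for 16 of 24 genes (median -0.22, limma camera adjusted p = 0.0459; adjusted p = 0.789 with an estimated correlation, unadjusted 0.395). Cd34 differed by -1.47 ± 0.67, the matrix protein gene Postn by -0.79 ± 0.18, the surface glycoprotein gene Cd200 by -0.80 ± 0.35 and the transcription factor gene Nfib by -0.46 ± 0.17. Without CSA replicate 1 these differences were -0.55 for Cd34, -0.70 for Postn, -0.36 for Cd200 and -0.44 for Nfib. Krt15, a bulge keratin, differed by -0.06 ± 0.18. Lgr5, a receptor of stem cells in several epithelia, was 1.22 and 3.70 in CSA against 2.70 and 3.02 in vehicle; its difference of -0.40 ± 0.88 turned to 0.14 after quantile normalization. CSA replicate 1 had the lowest median of the list (0.35), against 0.93, 0.53 and 1.02 for CSA replicate 2, vehicle replicate 1 and vehicle replicate 2. The call was lost without CSA replicate 1 (median -0.10, limma adjusted p = 0.821), without vehicle replicate 2 (median -0.07, 0.806, with the direction of the test turned), with arrays centred on their medians (0.0519) and on ranks (0.101). Without vehicle replicate 1 the median was -0.41 (limma adjusted p = 5.58e-05) and without CSA replicate 2 it was -0.34 (0.000441).

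Wnt pathway genes were lower in CSA, 28 of 35 (median -0.16, limma camera adjusted p = 0.0368; adjusted p = 0.789 with an estimated correlation, unadjusted 0.254). Axin2, which Wnt signalling induces, differed by -0.74 ± 0.23 and the receptor genes Fzd7 and Fzd1 by -0.98 ± 0.32 and -0.75 ± 0.28. The call was lost without vehicle replicate 1 (median -0.05, limma adjusted p = 0.203), CSA replicate 2 (median -0.10, 0.728) or vehicle replicate 2 (median -0.30, 0.0855), and without CSA replicate 1 the median was -0.27 (0.00425). Genes of BMP and TGF-beta signalling went both ways, 14 higher and 14 lower, with a median of -0.01 that was 0.003 after quantile normalization and 0.01 with arrays centred on their medians (limma camera adjusted p = 0.872). Ltbp1, which binds latent TGF-beta, differed by -1.85 ± 0.47 and the secreted antagonist gene Fst by -1.27 ± 0.39, while the BMP target Id3 was higher by 0.91 ± 0.24. The 14 markers of the hair germ, where activated progenitors lie, did not stand apart (6 higher, 8 lower, limma camera adjusted p = 0.872). Neither did the 16 genes of the inner root sheath and hair shaft (5 higher, 11 lower, 0.237). The keratin genes Krt17 and Krt25 of that list differed by -0.95 ± 0.35 and -0.51 ± 0.23.

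Among cell cycle genes, the G2 and M phase list was lower in CSA for 19 of 24 members (median -0.25, limma camera adjusted p = 0.0229; adjusted p = 0.789 with an estimated correlation, unadjusted 0.297). Mki67, the proliferation marker, differed by -0.48 ± 0.24, Ect2, needed for cytokinesis, by -0.51 ± 0.18 and the kinetochore gene Cenpf by -0.35 ± 0.15. The difference of Mki67 was -0.21 without vehicle replicate 1 and -0.74 without vehicle replicate 2. The call was lost without vehicle replicate 1 (median -0.12, limma adjusted p = 0.119), CSA replicate 2 (median -0.11, 0.886) or vehicle replicate 2 (median -0.30, 0.0855), and without CSA replicate 1 the median was -0.40 (0.000437). S phase genes were split, 12 higher and 12 lower, with a median of -0.003 that was 0.04 after quantile normalization and 0.02 with centred arrays (limma camera adjusted p = 0.872), with Chaf1b at 0.51 ± 0.18 and the DNA ligase gene Lig1 at -0.52 ± 0.20. Of the 22 cyclins, kinases and inhibitors of G1, 7 were higher and 15 lower (limma camera adjusted p = 0.4). Ccnd1 differed by -1.52 ± 0.45 and the other D-type cyclin gene Ccnd2 by -1.06 ± 0.37. Cdk4, their kinase, was -0.98 and 0.11 in CSA and 0.72 and -0.17 in vehicle, and its difference of -0.70 ± 0.51 was -0.16 without CSA replicate 1 and -0.26 without vehicle replicate 1. Rb1, which the kinase inactivates, differed by 0.69 ± 0.25.

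Genes of interfollicular epidermal differentiation, which mark cells outside the bulge, were lower in CSA for 16 of 20 members (median -0.75, limma camera adjusted p = 0.000675; adjusted p = 0.789 with an estimated correlation, unadjusted 0.326). Vehicle replicate 1 had the highest value for 16 of the 20. The suprabasal keratin gene Krt10 was 0.38 there and -0.59 on the other vehicle array, against -1.35 and -0.90 in CSA, and the cornified envelope gene Flg2 was 2.43 there and 0.11 on the other. Without vehicle replicate 1 the list's median was -0.05 (limma adjusted p = 0.715), and without vehicle replicate 2 it was -1.21 (4.57e-08). Of the 19 sebaceous and lipid synthesis genes 7 were higher and 12 lower (limma camera adjusted p = 0.237), with the triglyceride synthesis gene Dgat2 at -0.52 ± 0.15 and Sqle, of cholesterol synthesis, at -0.46 ± 0.18.

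Markers of other skin cells were tested as well. The 19 fibroblast markers were lower in CSA for 17 (median -0.16, limma camera adjusted p = 0.0318; adjusted p = 0.789 with an estimated correlation, unadjusted 0.304), with the collagen genes Col6a1 at -0.74 ± 0.28 and Col5a2 at -0.36 ± 0.19. The 15 endothelial markers were lower for 14 (median -0.15, limma camera adjusted p = 0.0445; adjusted p = 0.789 with an estimated correlation, unadjusted 0.479), with the growth factor receptor gene Kdr at -0.32 ± 0.16 and Egfl7 at -0.39 ± 0.26. Without vehicle replicate 1 the difference was -0.285 for Kdr and -0.087 for Egfl7. Vehicle replicate 1 had the highest median of both lists, 0.23 and 0.21, and without it neither passed (medians -0.11 and -0.03, limma adjusted p = 0.203 and 0.707). Both also failed without CSA replicate 2 (medians -0.09 and -0.07, limma adjusted p = 0.583 and 0.848) or vehicle replicate 2 (medians -0.25 and -0.29, 0.0751 and 0.0518), and the fibroblast list also failed without CSA replicate 1 (median -0.28, 0.0522). Immune cell markers (8 of 27 higher, limma camera adjusted p = 0.576), mast cell markers (2 of 12 higher, 0.354), melanocyte and Schwann cell markers (4 of 12 higher, 0.872, with the direction of the test turned by quantile normalization and by centring the arrays) and muscle, adipocyte and red cell markers (2 of 17 higher, 0.262) did not stand apart.

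Oxidative phosphorylation genes were higher in CSA, 23 of 28 (median 0.20, limma camera adjusted p = 9.46e-05; adjusted p = 0.789 with an estimated correlation, unadjusted 0.215). Cox7b, of respiratory complex IV, differed by 0.69 ± 0.18, Uqcrc2, of complex III, by 0.61 ± 0.24 and Ndufs3, of complex I, by 0.41 ± 0.16. Without CSA replicate 2 the median was 0.01 and the call was lost (limma adjusted p = 0.848), and without CSA replicate 1 the median was 0.43 (6.87e-08). Of 25 cytosolic ribosomal protein genes 13 were higher (limma camera adjusted p = 0.237), Rpl14 by 0.40 ± 0.19.

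Genes of the unfolded protein and integrated stress response were higher in CSA, 13 of 20 (median 0.18, limma camera adjusted p = 0.0445; adjusted p = 0.789 with an estimated correlation, unadjusted 0.14). Hspa5, the main chaperone of the endoplasmic reticulum, differed by 0.88 ± 0.30 and Xbp1, a transcription factor of the response, by 0.69 ± 0.25, while Sesn2 was lower by -0.84 ± 0.29. Vehicle replicate 1 had the lowest median, -0.51. The call was lost without CSA replicate 1 (median 0.17, limma adjusted p = 0.0782), vehicle replicate 1 (median 0.18, 0.707) or CSA replicate 2 (median 0.09, 0.416). It was also lost with quantile normalization (limma adjusted p = 0.0948), centred arrays (0.0672), the mean of a gene's rows (0.101) and ranks (0.0606). Of 23 immediate early and dissociation stress genes 13 were higher, with a median of 0.04 that was -0.03 after quantile normalization (limma camera adjusted p = 0.237; 4.28e-05 without CSA replicate 2), Ier2 by 0.92 ± 0.24; their median was 0.23 on CSA replicate 1 and -0.52 on CSA replicate 2.

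The measured genes of hormone and cytokine pathways did not stand apart. The prolactin receptor gene Prlr, listed under both hormone receptors and prolactin signalling, had no row naming it alone and was not analysed here. Of 15 steroid and hormone receptor genes 5 were higher and 10 lower (median -0.22, limma camera adjusted p = 0.237). The oxytocin receptor gene Oxtr differed by -0.50 ± 0.21 and the vitamin D receptor gene Vdr by 0.65 ± 0.39. The groups overlapped for Vdr, and its difference was 0.28 without CSA replicate 1 and 0.29 without vehicle replicate 1. That of Oxtr was -0.30 without vehicle replicate 1. Of 17 genes of prolactin and JAK-STAT signalling 7 were higher and 10 lower (limma camera adjusted p = 0.706), with Stat5b, which prolactin activates, at -0.47 ± 0.25 and Pias3, an inhibitor of STAT proteins, at 0.53 ± 0.21. Of 17 interferon response genes 7 were higher and 10 lower (limma camera adjusted p = 0.504), with Irf9 at 0.38 ± 0.19. The median and the camera direction differed in sign for 4 lists that did not pass, namely S phase, BMP and TGF-beta, prolactin and JAK-STAT, and interferon response.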

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

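No alternative was chosen after the data were seen, apart from the exchange of the planned mean-variance trend for the fit without it. With 2 arrays per group and no scanner signal, neither small differences nor dim genes can be resolved here. limma called 0 genes in all 14 alternatives, with smallest adjusted p from 0.276 to 1; at an unadjusted p under 0.05 the trend gave 547 genes, the robust trend 467 and the unmoderated test 540. The count of 1177 genes 1.5-fold apart was within 1.5 times with quantile normalization, centred arrays and the mean of rows, was 344 at 2-fold, and was 645 and 547 with the filters at the 25th and 50th percentile, where fewer genes are counted. Without 1 array it ranged from 1565 to 3371, since fewer arrays overlap less.

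Of the 9 lists called, 6 passed with the replicate block, 8 with quantile normalization, 7 with centred arrays, 8 with the mean of rows, 7 on ranks, 3 and 2 with the filters, and 0 with an estimated correlation. Without 1 array 3 to 7 lists passed in all, of which 6 were among the 9 without CSA replicate 1, 3 without vehicle replicate 1, 2 without CSA replicate 2 and 3 without vehicle replicate 2. Deviations from the group means of arrays with the same number had r = 0.216 across rows. The block changed no gene call and ended the calls of the bulge (adjusted p = 0.0604), Wnt (0.0604) and unfolded protein (0.107) lists.

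Where the direction of a list turned, the cause was not tested and the medians were as follows. The hair germ list had 0.283 with both filters (7 genes left) and -0.09 on ranks, where only the test's direction turned, and -0.136 to 0.18 without 1 array. With the filter at the 25th percentile the G1 list had -0.118 (10 genes left), the sebaceous list 0.155 (5) and the immediate early list -0.116 (8). With that at the 50th they had 0.144 (6), 0.157 (4) and -0.102 (7), the hormone receptor list 0.042 (4), the interferon list -0.042 (5) and the ribosomal list -0.036 (4); 1 gene was left of the G2 and M list, Top2a at 0.171, which is no value of the list; the S phase list had no gene left and gave no value. The melanocyte list had -0.004 with quantile normalization and -0.001 with centred arrays. Without 1 array the medians ran from -0.411 to -0.071 for bulge markers, -0.32 to -0.038 for hair shaft, -0.123 to 0.062 for S phase, -0.036 to 0.093 for calcineurin and NFAT, -0.103 to 0.043 for prolactin and JAK-STAT, -0.02 to 0.02 for BMP and TGF-beta, -0.221 to 0.476 for immediate early, -0.197 to 0.03 for immune, -0.185 to 0.024 for mast cell, -0.13 to 0.018 for melanocyte, and -0.211 to 0.018 for muscle and adipocyte genes.

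Of 100 named genes recomputed without each array in turn, 54 had a difference that moved by over 1.5 times. Among these 100 genes the sign held under every alternative but those that follow. Serpinb3a, Serpinb3c and Serpinb3d, whose differences were near 0, were not among them. Quantile normalization gave -0.08 for Rcan1 and 0.136 for Lgr5. The mean of a gene's rows gave -0.378 for Top2a. Without 1 array the differences ran from -0.442 to 0.624 for Nfatc1, -0.033 to 0.265 for Ppp3ca, -0.602 to 0.473 for Ppp3cb, -0.191 to 0.323 for Rcan1, -0.697 to 0.385 for Itga6, -0.164 to 0.052 for Krt15, -1.635 to 0.845 for Lgr5, -0.03 to 3.689 for Fkbp5, -0.539 to 2.369 for Klf9, -0.664 to 2.696 for Errfi1, -0.059 to 0.401 for Top2a, -0.601 to 1.057 for Per1, -0.269 to 0.674 for Nr1d1, -0.718 to 1.319 for Ciart and -0.031 to 2.448 for Ddit4.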

Other observations

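The tests of the epidermal list without vehicle replicate 1, of the bulge list and of the glucocorticoid genes on each CSA array by itself were chosen after the result was seen; the other tests were written down before it, and the genes named here were chosen after their values were seen.

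All 4 arrays shared features against the authors' baseline, whatever the treatment. In all, 14 genes stood above 1 on every array and 10 below -1. Cd34 lay between 1.75 and 4.25, Lgr5 between 1.22 and 3.70, the keratin gene Krt24 between 1.92 and 2.92, Il31ra between 1.71 and 3.46 and Id2, an inhibitor of differentiation factors, between 1.21 and 1.53. Below the baseline were Ly6d (-2.84 to -1.15), the decoy interleukin 1 receptor gene Il1r2 (-3.55 to -1.17) and Tgm3, a transglutaminase of the cornified layer (-1.73 to -1.06). Of the 24 bulge markers 19 were above 0 on all 4 arrays and 0 below, and of the 24 G2 and M phase genes 0 were above and 8 below. The 14 glucocorticoid-induced genes and the clock genes described next were in no list of the report.

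Several clock genes differed between the groups, and none passed over all genes. Arntl, the activator at the core of the circadian clock, was 0.92 and 0.47 in CSA and -1.04 and -0.99 in vehicle (1.71 ± 0.22), and its target Dbp was lower in CSA (-1.15 ± 0.22); limma's adjusted p was 0.999 for both. A hypothesis of a coordinated clock shift was tested on 12 further clock genes, each with a direction set in advance. Of these 9 went that way, 6 without overlap, among them Per3 (-0.70 ± 0.17), Hlf (-0.69 ± 0.17), Bhlhe41 (-0.72 ± 0.29) and Tef (-0.59 ± 0.32), while Per1 (0.23 ± 0.60), Nr1d1 (0.20 ± 0.38) and Ciart (0.30 ± 0.89) did not. Their median in the expected direction was 0.33, at percentile 99.96 of random sets, and it lay between 0.28 and 0.65 for each CSA array against each vehicle array. Yet the CSA arrays parted on several genes. Per1, Per2, Nr1d1 and Ciart, expected lower, stood above both vehicle arrays on CSA replicate 1 (1.40, 0.69, 0.61 and 0.99). On CSA replicate 2 they were -0.26, -0.53, -0.33 and -0.48. Cry1, expected higher, was 0.45 and -0.32 on the CSA arrays. Nfil3, one of the 12, had been seen before; without it the percentile was 99.85. The random sets take genes as independent, which clock genes are not. Differences that both CSA arrays share may reflect the treatment or the hour of collection. The labels used here do not give that hour, and neither was tested.

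Serpina3n (2.71 ± 0.78), Cebpd (1.54 ± 0.84), Nfil3 (1.62 ± 0.70) and Hk2 (1.76 ± 0.66) were higher on both CSA arrays, with a limma adjusted p of 0.999 for each. CSA replicate 1 had the higher value of the CSA arrays for all 4, 3.81 against 1.61 for Serpina3n and 2.77 against 0.39 for Cebpd. Without it their differences were 1.61, 0.35, 0.87 and 0.95 in the same order. A glucocorticoid or fasting response was put forward as a hypothesis and tested on 14 genes such hormones induce, of which 12 were higher; their median over both CSA arrays, 0.82, met the prediction (percentile 100.0 of random sets). Read array by array, that median rested on CSA replicate 1. There the genes stood at a median of 1.54 above the vehicle mean (percentile 100.0), and on CSA replicate 2 at -0.13 (percentile 17.53). The random sets take genes as independent, which genes induced together are not. Fkbp5, a standard target of the glucocorticoid receptor, was 3.22 on CSA replicate 1 and -0.50, -0.45 and -0.48 on CSA replicate 2 and the vehicle arrays, and Klf9, Errfi1 and Ddit4 were above 2 there and below 0.1 elsewhere. The values argue against such a response in both CSA samples, and a response in the 1 sample may be a candidate explanation for its part of the pattern. Why it differed from the other was not tested.

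Serpinb11, Serpinb10 (-2.96 ± 0.91) and Serpinb2 (-1.68 ± 0.25), which lie in 1 cluster of serine protease inhibitor genes, were lower on both CSA arrays. If the cluster changed as a whole, its other genes from Serpinb5 to Serpinb8 would be lower too. All 8 were lower, Serpinb8 by -0.71 ± 0.25, but Serpinb3a, Serpinb3c and Serpinb3d by only -0.01 to -0.02, less than the median of all genes (-0.04). The median of the 8, -0.19, lay at percentile 5.05 of runs of as many neighbouring genes, short of the bound of 2.5 set in advance. Whether the cluster shares a change or these 3 genes stand alone cannot be told apart with 8 genes on 4 arrays, several of them near 0 on all arrays.

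The epidermal differentiation list was lower in CSA (limma camera adjusted p = 0.000675; adjusted p = 0.789 with an estimated correlation). Skin does not use olfactory and vomeronasal receptor genes. An offset of vehicle replicate 1 that raises genes without expression would move the list no more than it moves them. The list's median change lay at percentile 0.0 of random receptor sets of its size. That argues at most against an offset of the size that receptor genes show. The sets take genes as independent, while the list's members had an estimated correlation of 0.534. Without vehicle replicate 1 the median change was -0.045, and 16 of 20 members were highest on that array, the keratin gene Krt1 at 0.10 there against -2.15, -2.31 and -2.72 elsewhere. Of the members not highest there, Calml3 was 2.34 on vehicle replicate 1 and 2.40 on vehicle replicate 2, against 0.24 and 1.67 in CSA. Tgm3 was -1.33 on vehicle replicate 1 and -1.06 on CSA replicate 1. For the members highest on vehicle replicate 1 only, a candidate explanation is RNA of differentiated keratinocytes in that sample, cells the sort for CD34 should remove. An effect of CSA on such cells stays untested.

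Endothelial and fibroblast markers were lower in CSA (limma camera adjusted p = 0.0445 and 0.0318; adjusted p = 0.789 with an estimated correlation for both), and without vehicle replicate 1 their medians were -0.03 and -0.11. The same offset was tested on the endothelial list: the 1193 receptor genes stood only 0.02 above all genes on vehicle replicate 1. The list's change lay at percentile 0.01 of random receptor sets. That argues at most against an offset of the size that receptor genes show. The sets take genes as independent, while the list's members had an estimated correlation of 0.598. Marker lists of other cells were also highest on vehicle replicate 1, with medians of 0.18 for mast cells and 0.146 for immune cells. Muscle, adipocyte and red cell markers had 0.178 there, and melanocyte and Schwann cell markers 0.115. An offset that such markers share stays open, and what set this array apart was not tested. An effect of CSA stays open as well. Endothelial and fibroblast levels stayed near the baseline, with medians from -0.11 to 0.23 on the 4 arrays.

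The bulge marker list was lower in CSA (limma camera adjusted p = 0.0459; adjusted p = 0.789 with an estimated correlation) and lowest on CSA replicate 1, where the members' median was -0.31 against vehicle replicate 1 and -0.50 against vehicle replicate 2. A list lower on that array alone cannot be told apart from one lower on both, since the vehicle arrays disagree and nothing pairs the arrays. CSA replicate 2 minus vehicle replicate 2 had a median of -0.18 (95% interval over members -0.41 to -0.055). CSA replicate 2 minus vehicle replicate 1 had one of 0.15 (-0.25 to 0.48). These intervals take members as independent and do not measure the spread between arrays. The list median of CSA replicate 2 (0.93) lay between those of the vehicle arrays (0.53 and 1.02). If the unknown baseline had the levels of other skin cells, such cells in the CSA replicate 1 sample would bring its values nearer to 0: compared with CSA replicate 2, the 110 genes above 1 in both vehicle arrays were lower there by a median of -0.88 and the 38 genes below -1 were higher by 0.402, while Krt1 (-2.72) and Krt10 (-1.35) were farther below 0 there than on any other array. This cannot be told apart from the choice of genes on the vehicle arrays, whose mean had r = 0.327 with CSA replicate 2 and 0.164 with CSA replicate 1 across genes, which are not independent. An effect of CSA on the stem cells themselves stays open.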
